A study of Mus musculus with 11 samples.

How the data were processed

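RNA of the neocortex of mouse embryos at embryonic day 18 was compared on 11 two-colour oligonucleotide arrays, per the labels. Each array set RNA of 1 null mutant embryo against RNA of wild-type embryos. The design text speaks of 11 pooled biological replicates as the partner, read here as 1 common pool of wild-type RNA. Per the labels, the mutant RNA carried Cy3 on arrays 1, 2, 6, 7, 8 and 10 and Cy5 on arrays 3, 4, 5, 9 and 11. The wild-type channel of arrays 1 and 6 is given as day 14 in one label and as day 18 in another. Arrays were grouped and numbered from the labels alone.

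The values used are the log ratios the authors deposited, 1 per probe and array, treated as log2. Their log base, background correction, normalization within arrays and direction are not given in the sources used here. Base 2 is assumed as the usual one for two-colour ratios; with natural logs every fold would be larger. The 11 columns have means between -0.00405 and 0.00298 and medians between -0.05 and 0.04, so each looks centred on its mean. A uniform shift of all transcripts would not be visible in such values. Of the 6856 probes, 153 had no value on any array and 4111 had values on all 11; 17.3% of the cells were empty, for reasons not given in the sources used here. Scanner intensities were not used here, so no filter on dim probes was possible and signal over background is unknown. The arrays carried 4822 to 6316 values each, and the number of arrays limits the precision.

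Probe names came from the platform's annotation table. It gave 1 symbol for 6269 probes, several for 6 and none for 581; 6250 symbols were updated through their Entrez identifiers to a RefSeq gene table of assembly GRCm38.p6, and 6041 distinct genes resulted. The planned check of the mutated gene and of its neighbours is not reported here. Probes with several symbols were left unnamed. Gapdh alone had 78 probes, which count as separate probes in counts of probes and as 1 gene in counts of genes.

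Probes with values on at least 8 arrays and at least 3 of each dye orientation were tested, which kept 5399 probes and 4812 genes. A linear model with the mean ratio and a dye term (Cy5 plus, Cy3 minus) was fitted with limma 3.58.1 in R 4.3.3, with moderated variances and Benjamini-Hochberg adjustment at 0.05. All tests were two-sided. Since the wild-type RNA was read as 1 control sample, the mean ratio was tested against 0, which leaves out the spread among wild-type pools. Errors given with log2 ratios are standard errors of that model. For gene lists, probes of 1 gene were averaged and the moderated statistics of list members were compared with those of all other genes by camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the rotation test fry, both on genes with values on all 11 arrays, were alternatives.

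The 30 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are the 12 lowest and the 12 highest log2 ratios among probes past the threshold with 1 symbol and the same sign on at least 10 arrays, 1 probe per gene, and up to 4 members of smallest p in each list; where probes of a named gene disagree in sign, each is given. Other genes that are named were chosen after their values were seen. The lists on neuropeptides and dense core granules were drawn up knowing that the study is concerned with such genes, so they are not independent evidence of a direction.

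The alternatives dropped the dye term; used the arrays of 1 dye orientation; left out arrays 1 and 6, or each array in turn; centred, scaled or weighted the arrays otherwise; changed the probes tested; used robust or unmoderated variances, stricter thresholds or an exact sign-flip permutation test; and reversed the Cy5 arrays. Leaving out arrays 9 and 10, exchanging their dye orientation, leaving out array 4, and leaving out arrays 3, 4 and 10 were added after seeing the data. In the closing section, means of gene lists were compared by permuting genes between lists, and the interval of a median came from a bootstrap over genes. Figures were drawn from the same values.

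The fit was tested on simulated data with the spreads, empty cells and dye terms of the 5399 real probes and 200 changed probes. For the comparison of null with wild type, it recovered 52% of probes changed by 0.20 on the log2 scale, 66% at 0.30, 96% at 0.50 and 100% at 1.00, and 12 of its 169 calls were false. In 30 simulated lists of 20 members, camera called the 3 lists in which 10 members were shifted by 0.30 and 0 of the others. The simulated noise was independent between probes and arrays. In the real data the estimated correlation within a list reached 0.67, for ribosomal proteins. The false calls of the simulation therefore do not carry over to correlated genes.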

Results

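Gene expression was measured in the neocortex of mouse embryos at embryonic day 18 of a null mutant described in the record as synaptically silent. The comparison asks which transcripts depend on synaptic activity before birth. Each of 11 arrays compared 1 null embryo with pooled wild-type RNA, with the mutant RNA in Cy3 on 6 arrays and in Cy5 on 5. The arrays carried 4822 to 6316 values each, and 5399 probes for 4812 genes were tested.

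The direction of the deposited ratios is not given in the sources used here. It was taken as null over wild type, which is likely from Xist alone. Xist, the transcript of the inactive X chromosome of females, had log2 ratios between -7.37 and -4.18 on arrays 1, 2, 3, 5, 8 and 10, of both dye orientations. It had ratios between 0.00 and 0.67 on arrays 6, 7, 9 and 11 and no value on array 4. The reverse direction would need a wild-type pool without females. Kdm5d, a Y-linked gene, was positive on arrays 1, 2, 3, 4, 8 and 10, at 0.65 to 1.34, and lay between -0.86 and 0.16 on the others. These positive ratios do not separate the directions, since the reverse direction with a pool of males only would give them too. Null over wild type would make Kdm5d clearly negative in female nulls. On arrays 6, 7, 9 and 11, where Xist was not low, Kdm5d lay at -0.32, -0.34, -0.86 and 0.16. On array 5 the 2 genes disagree, with Xist at -5.55 and Kdm5d at -0.61. The lowest Spearman correlation across probes between any pair of arrays, without Xist, was -0.08, so no pair ran clearly in opposite directions. This bears on whether the arrays share a direction, not on which one it is. Log base 2 is assumed for every value.

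Expression in the null neocortex differed from the wild-type pool for many genes, mostly by small amounts. Among called probes with 1 symbol and the same sign on at least 10 arrays (the fixed rule), the lowest ratios were those of Cdc42ep5, an effector of the GTPase Cdc42, which fell by 1.49 ± 0.07 (SE, n = 11), the acid-sensing channel Asic1, which fell by 1.47 ± 0.09 (n = 10), and the calcium-binding protein Calb1, which fell by 1.46 ± 0.10 (n = 11). The highest under this rule was that of the astrocyte filament gene Gfap, which rose by 1.48 ± 0.11 (n = 11), followed by Laptm5, a lysosomal membrane protein of myeloid cells, at 1.01 ± 0.06, and the lipid carrier Apoe, at 0.95 ± 0.07. In all, limma called 1545 of 5399 probes at an adjusted p of 0.05, of which 791 were higher and 754 lower. At the level of genes, 699 of 4812 were higher and 687 lower. Only 23 genes were higher and 58 lower by at least 1.5-fold, and 3 and 14 by at least 2-fold.

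The other genes with the lowest ratios under the fixed rule were the proteoglycan Spock3 (-1.41), the huntingtin partner Hap1 (-1.40), the granin Scg2 (-1.12), the endocytic GTPase Dnm1 (-1.07), the ephrin receptor Epha4 (-1.07), the vesicular GABA transporter Slc32a1 (-1.02), the calmodulin regulator Pcp4 (-1.01), the GTPase Rragc (-0.97) and the serotonin receptor Htr4 (-0.93). Each of the 12 genes was lower on every array that measured it, 11 arrays for all but Asic1 and Epha4, which had 10. Their standard errors lay between 0.05 and 0.10 and their adjusted p between 2.8e-09 and 5.8e-06. The other genes with the highest ratios under the rule were the cholesterol exporter Abca1 (0.89), the complement genes C1qc (0.88) and C1qa (0.73), the lysosomal protease Ctss (0.87), Atn1 (0.80), Fkbp8 (0.70), transferrin Trf (0.65), Thbd (0.63) and the macrophage mannose receptor Mrc1 (0.63). They were higher on every array that measured them, except Atn1, which was higher on 10 of 11. The adjusted p of the 12 highest lay between 5.1e-08 and 0.00080. The other probes of Trf had ratios of 0.59, 0.46 and 0.64.

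**Figure D1:**
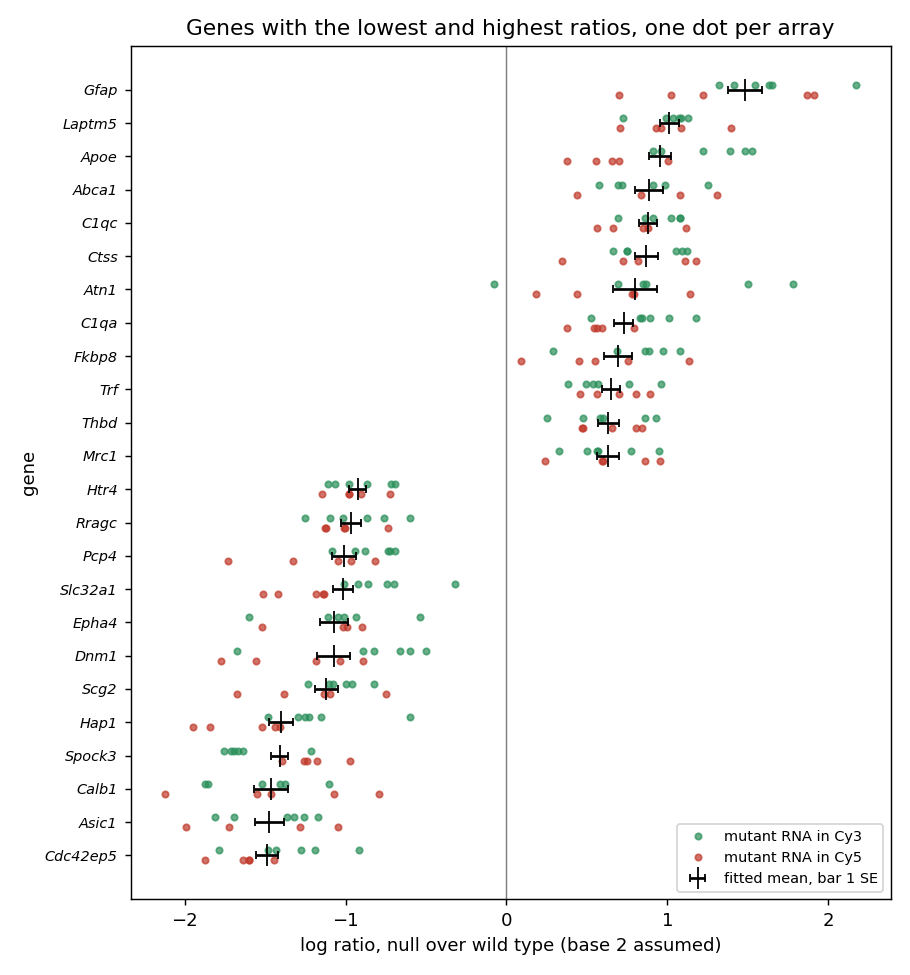
Log ratios (null over wild type, base 2 assumed) of the 12 lowest and 12 highest genes under the fixed rule, with 1 dot per array coloured by the dye of the mutant RNA, and the fitted mean with a bar of 1 SE. Cdc42ep5 (-1.49) and Gfap (1.48) lie at the ends, and every dot lies on the side of its mean except 1 dot of Atn1.

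The count of changed probes was 468 on the 5 Cy5 arrays alone, and 811 at an adjusted p of 0.01.

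Genes of the synaptic vesicle machinery were lower as a set, though not alike on all arrays, and some members rose. Of 36 measured members, 17 fell, 5 rose and 14 did not pass, with 19 and 5 when adjusted over the list alone. The median was -0.21, the adjusted p of camera 9.1e-05, and adjusted p = 0.168 with an estimated correlation. Slc32a1 fell by 1.02 ± 0.06, the ATPase Nsf, which takes apart SNARE complexes, fell by 0.71 ± 0.06, Dnm1 fell by 1.07 ± 0.10 and the priming factor Cadps fell by 0.41 ± 0.05. The 5 members that rose were the synaptotagmins Syt7 (0.45) and Syt11 (0.24), Stxbp2 (0.30), Stxbp3 (0.19) and Syn3 (0.56). The median of the list differed between arrays. It was -0.46 on array 3, -0.53 on array 4 and -0.47 on array 10, and lay between -0.21 and 0.01 on the other 8. Without arrays 3, 4 and 10 it was -0.086, with an adjusted p of 0.024.

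Channel and glutamate receptor genes were also lower as sets. Of 28 voltage-gated channel genes 12 fell and 3 rose, against 13 and 3 when adjusted over the list alone (median -0.13, adjusted p = 0.0011, and adjusted p = 0.036 with an estimated correlation). The calcium channel subunits Cacna2d2 (-0.62 ± 0.05) and Cacna2d3 (-0.50 ± 0.06) and the potassium channels Kcnd2 (-0.54 ± 0.05) and Kcnh2 (-0.39 ± 0.05) were among those that fell. Of 24 genes of glutamate receptors and the postsynaptic density, 9 fell and 4 rose, against 10 and 4 when adjusted over the list alone (median -0.096, adjusted p = 0.019, and adjusted p = 0.168 with an estimated correlation). The scaffold Shank3 fell by 0.54 ± 0.05, Camk2d by 0.74 ± 0.07, Grik1 by 0.56 ± 0.06 and Nrxn2 by 0.43 ± 0.05, whereas the receptor subunits Grin2a (0.31) and Gria2 (0.22) rose. On the 6 Cy3 arrays alone this list had a median of -0.038 and an adjusted p of 0.321. The median of the channel list was lowest on arrays 3, 4 and 10 (-0.25, -0.22 and -0.26, against -0.18 to -0.05 on the other 8). That of the glutamate receptor list was -0.18, -0.21 and -0.20 there, and -0.19 to 0.00 on the others. Without these 3 arrays the lists had medians of -0.13 (adjusted p = 0.0046) and -0.092 (adjusted p = 0.048).

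Among 25 genes of GABAergic neurons and GABA receptors, 6 fell and 2 rose, the same counts as when adjusted over the list alone, and the list did not pass (median -0.031, adjusted p = 0.116). The receptor subunit Gabra5 fell by 0.85 ± 0.04 and Gabrb1 fell by 0.42 ± 0.04, beside Slc32a1 (-1.02) and Calb1 (-1.46). Among 35 genes of the neuronal cytoskeleton and of axon growth, 7 rose and 7 fell, against 7 and 8 when adjusted over the list alone (median -0.060, adjusted p = 0.196). Gap43, a growth cone protein, fell by 0.50 ± 0.04, the adhesion molecule Cntn1 by 0.48 ± 0.04, Epha4 by 1.07 and the neuronal enolase Eno2 by 0.40 ± 0.06.

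Activity-regulated immediate early genes did not move as a set. Of 31 measured members, 6 fell, 3 rose and 22 did not pass, the same counts as when adjusted over the list alone (adjusted p = 0.835). The median was 0.016 and the mean -0.024, and camera pointed up. The neurotrophin Bdnf fell by 0.61 ± 0.09, the regulator of G protein signalling Rgs2 by 0.60 ± 0.08 and the transcription factor Klf6 by 0.37 ± 0.06, whereas the phosphatase Dusp1 rose by 0.32 ± 0.04. Egr1 had a ratio of 0.17 ± 0.12 (n = 10, adjusted p = 0.299) and Fosb one of -0.03.

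Of 17 dense core granule and prohormone processing genes, 4 fell and 1 rose, the same counts as when adjusted over the list alone, and the list missed the threshold (median -0.086, adjusted p = 0.052, and adjusted p = 0.166 with an estimated correlation). Scg2, a granule protein and precursor of secretoneurin, fell by 1.12 ± 0.07, Bdnf by 0.61, and the granule priming factors Cadps by 0.41 and Cadps2 by 0.25, while Scg5 rose by 0.30 ± 0.06. Of 18 neuropeptide precursors 4 fell and 1 rose, again the same adjusted over the list alone (median -0.037, adjusted p = 0.299). Cartpt fell by 0.55 ± 0.08 (n = 8), Npff by 0.29 ± 0.06 and Nppc by 0.21 ± 0.04, whereas Pomc rose by 0.22 ± 0.05. Npy had a ratio of 0.03 ± 0.05. The dense core granule list passed when array 1, 2, 3, 4, 6, 7, 8 or 9 was left out, with camera adjusted p from 0.023 to 0.047. It then held 14 to 16 members. The fall was seen in 1 dye orientation only. Medians of single arrays lay between -0.27 and -0.17 on the Cy3 arrays and between -0.063 and 0.076 on the Cy5 arrays. On the Cy5 arrays alone the camera adjusted p was 0.472. These lists were chosen knowing the subject of the study and are not independent evidence of a direction.

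Neurotrophic and growth factors and their receptors went both ways. Of 25 members, 7 fell and 6 rose, against 7 and 8 when adjusted over the list alone (adjusted p = 0.928). The median was 0.014, whereas the mean was -0.029 and camera pointed down. The neurotrophin receptor Ntrk3 fell by 0.47 ± 0.04 as the mean of 2 probes that differ, probe 307 at -0.84 and probe 2558 at -0.10 (adjusted p = 0.242). Fgf1 fell by 0.61 ± 0.08 and Bdnf by 0.61, while Ntrk2, the receptor of Bdnf, rose by 0.28 ± 0.04.

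The median marker of microglia and macrophages was higher on every array, though not every member rose. Of 18 measured members 14 rose and 3 fell, the same counts as when adjusted over the list alone (median 0.59, adjusted p = 1.6e-07, and adjusted p = 0.036 with an estimated correlation). Laptm5 rose by 1.01, C1qc by 0.88, Ctss by 0.87 and C1qa by 0.73. The 3 that fell were Itgam (-0.18, lower on 11 of 11 arrays), Coro1a (-0.28) and Ptprc (-0.21), each of the latter lower on 10 of 11. Aif1 did not pass, at -0.0067 (adjusted p = 0.913). The medians of single arrays lay between 0.33 and 0.57. With replicate 1, 2, 3, 5, 6, 8 or 11 left out, the median was between 0.26 and 0.32 over 14 or 15 members, since members with values on few arrays then left the list.

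Astrocyte markers were higher as well. Of 15 members, 7 rose and 1 fell, the same as when adjusted over the list alone (median 0.16, adjusted p = 0.0040, and adjusted p = 0.036 with an estimated correlation). Gfap rose by 1.48, Apoe by 0.95 and the gap junction gene Gja1 by 0.50 ± 0.08, whereas the glutamate transporter Slc1a3 fell by 0.27 ± 0.06. Markers of the meninges and choroid plexus rose in 7 of 16 members and fell in 1, the same adjusted over the list alone (median 0.20, adjusted p = 0.0018, and adjusted p = 0.20 with an estimated correlation). Ogn rose by 0.58 ± 0.07 (n = 10), Col1a1 by 0.42 ± 0.08, Mgp by 0.29 ± 0.05 (n = 8) and Igfbp2 by 0.19 ± 0.05. Ttr, the main product of the choroid plexus and chosen after its values were seen, had a ratio of 1.505 ± 0.62 (adjusted p = 0.085) and ranged from -1.78 to 5.05 over the arrays.

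The vascular, oligodendrocyte and erythroid lists did not pass. Vascular markers rose in 3 of 20 members and fell in 1, with 2 and 1 adjusted over the list alone (median 0.049, adjusted p = 0.390), among them Abcb1a (0.23), Abcc9 (0.27), Kcnj8 (0.17) and Rgs5 (-0.31). Oligodendrocyte lineage markers rose in 3 of 12 and fell in 2, also when adjusted over the list alone (median 0.030, adjusted p = 0.661), with Sox10 (0.31) and Cldn11 (0.34) higher and Olig1 (-0.37) and Mag (-0.27) lower. Of 8 erythroid markers only Car2 (-0.22 ± 0.06) passed, also adjusted over the list alone (median -0.041, adjusted p = 0.529). Of the 4 sex-linked genes measured, Xist alone passed over all genes (-3.31 ± 0.91, lower on 6 of 10 arrays), and 1 more when adjusted over the list alone. The median of that list was 0.11, its mean -0.70, and camera pointed up (adjusted p = 0.800).

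**Figure D2:**
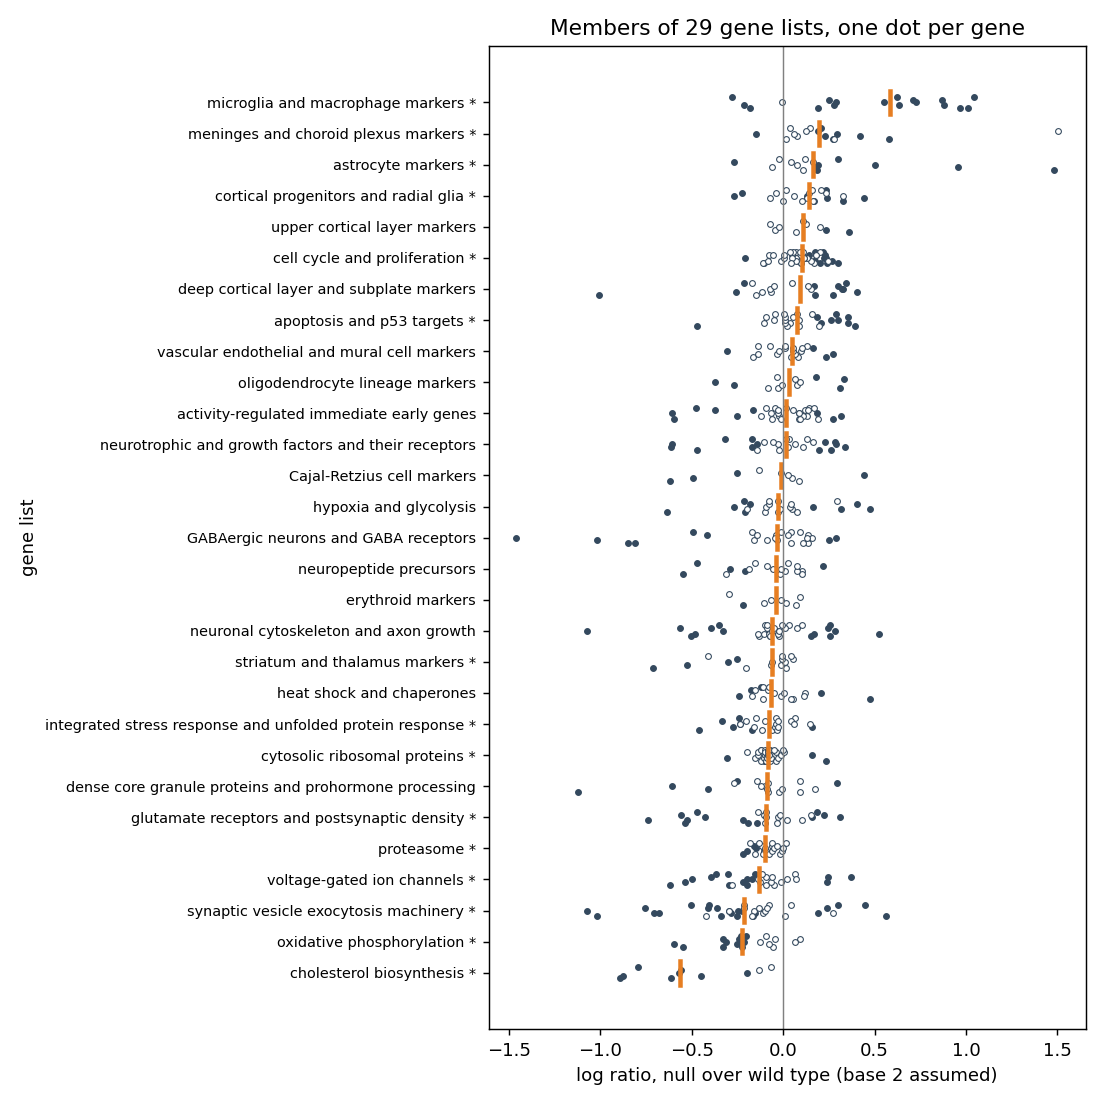
Log ratios (null over wild type, base 2 assumed) of the measured members of 29 gene lists, with filled dots for genes at an adjusted p under 0.05, orange bars for list medians and a star for lists that camera called with the preset correlation. The medians run from -0.56 for cholesterol biosynthesis to 0.59 for microglia and macrophage markers.

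Genes of dividing cells and progenitors were slightly higher. Of 44 cell cycle genes 13 rose and 1 fell, against 15 and 1 adjusted over the list alone (median 0.10, adjusted p = 0.0011, and adjusted p = 0.20 with an estimated correlation). Rrm2 rose by 0.30 ± 0.06, Cdk2 by 0.27 ± 0.05, Mcm5 by 0.22 ± 0.05 and Hmgb2 by 0.23 ± 0.06, while Ccnd1 fell by 0.21. Of 21 markers of cortical progenitors and radial glia, 6 rose and 2 fell, against 7 and 2 adjusted over the list alone (median 0.14, adjusted p = 0.019, and adjusted p = 0.262 with an estimated correlation). Prom1 rose by 0.33 ± 0.04 and Eomes, a gene of intermediate progenitors, by 0.44 ± 0.06, whereas Slc1a3 fell by 0.27 and Tnc by 0.23. On the 5 Cy5 arrays alone the progenitor list had a median of 0.0080 and an adjusted p of 0.236.

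Cortical layer genes did not pass as sets. Of 20 markers of deep layers and subplate, 8 rose and 3 fell, against 9 and 4 adjusted over the list alone (median 0.093, adjusted p = 0.299). Crym rose by 0.40 ± 0.06, Fezf2 by 0.32 ± 0.05 and Tbr1 by 0.30 ± 0.05, and Pcp4 fell by 1.01. Of 9 upper layer markers 2 rose, also adjusted over the list alone, namely Pou3f2 (0.36 ± 0.08) and Pou3f1 (0.24 ± 0.05) (median 0.11, adjusted p = 0.112, and adjusted p = 0.318 with an estimated correlation). Without array 10 the upper layer list had a median of 0.10 and passed with an adjusted p of 0.029. Of 9 Cajal-Retzius markers 3 fell and 1 rose, also adjusted over the list alone (median -0.011, adjusted p = 0.262), with Cacna2d2, Calb2 (-0.49) and Ebf1 (-0.25) lower and Eomes higher.

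Markers of striatum and thalamus, which neighbour the neocortex in dissection, fell in 4 of 15 members and rose in 0, also adjusted over the list alone (median -0.063, adjusted p = 0.020, and adjusted p = 0.166 with an estimated correlation). The 4 were Ppp1r1b (-0.71 ± 0.05), Zic1 (-0.53 ± 0.07), Isl1 (-0.30 ± 0.04) and Ebf1 (-0.25 ± 0.05). The dopamine receptor Drd2 had a ratio of -0.06 ± 0.05. On the 6 Cy3 arrays alone the median was -0.13 and the adjusted p 0.108, and without array 11 the median was -0.040.

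Genes of cholesterol biosynthesis had the lowest median of the lists. Of 10 measured members 8 fell and 0 rose, with 9 lower when adjusted over the list alone (median -0.56, adjusted p = 7.9e-09, and adjusted p = 0.0054 with an estimated correlation). Nsdhl fell by 0.89 ± 0.05, mevalonate kinase Mvk by 0.87 ± 0.06, the lanosterol demethylase Cyp51 by 0.57 ± 0.04 and the reductase Dhcr7 by 0.56 ± 0.04, each on 11 of 11 arrays. The median lay between -0.66 and -0.36 on single arrays. Ebp (-0.13) and Srebf2 (-0.06), the gene of the regulator of the pathway, did not pass.

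**Figure D3:**
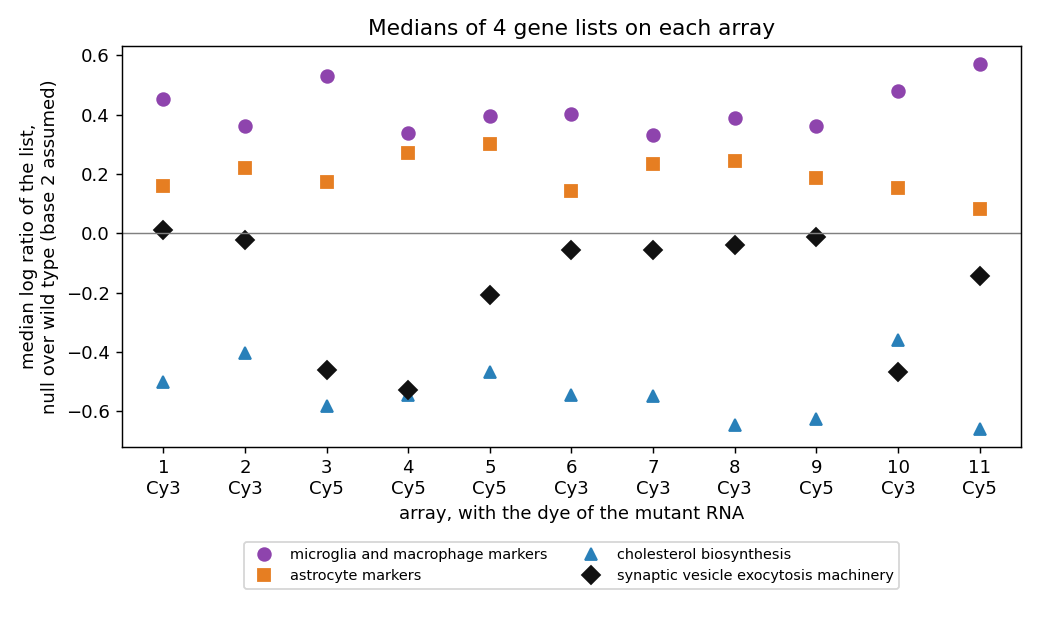
Median log ratio (null over wild type, base 2 assumed) of 4 gene lists on each of the 11 arrays, with the dye of the mutant RNA below the array number. Microglia markers lie between 0.33 and 0.57 and cholesterol genes between -0.66 and -0.36 on all arrays. Synaptic vesicle genes lie at -0.46, -0.53 and -0.47 on arrays 3, 4 and 10, at -0.21 and -0.14 on arrays 5 and 11, and between -0.055 and 0.01 elsewhere.

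Of 19 genes of oxidative phosphorylation 12 fell and 0 rose, against 13 and 0 adjusted over the list alone (median -0.22, adjusted p = 0.00016, and adjusted p = 0.312 with an estimated correlation). Cytochrome c, Cycs, fell by 0.55 ± 0.07, the cytochrome oxidase subunit Cox5a by 0.60 ± 0.08, the complex I subunit Ndufa1 by 0.31 ± 0.04 and Cox5b by 0.24 ± 0.05. Of 23 proteasome genes 4 fell and 0 rose, also adjusted over the list alone (median -0.098, adjusted p = 0.013, and adjusted p = 0.670 with an estimated correlation), namely Psmb5 (-0.22), Psmc2 (-0.20), Psmd2 (-0.15) and Psmc1 (-0.16). Of 40 ribosomal protein genes only 3 passed, also adjusted over the list alone: Rpl22 (0.23) and Rpl23 (0.16) rose and Rps29 fell by 0.31 (median -0.083, adjusted p = 0.033, and adjusted p = 0.771 with an estimated correlation). The ribosomal call was lost when array 1, 3, 6, 7, 9 or 11 was left out, with medians from -0.080 to -0.056 and adjusted p from 0.060 to 0.214, and without arrays 1 and 6 the proteasome list had an adjusted p of 0.086.

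Genes of apoptosis and p53 targets rose in 8 of 25 members and fell in 1, also adjusted over the list alone (median 0.074, adjusted p = 0.019, and adjusted p = 0.166 with an estimated correlation). The death receptor genes Tnfrsf1a (0.35 ± 0.06) and Fas (0.36 ± 0.07) and the cyclin Ccng1 (0.26 ± 0.04) rose, while the cell cycle inhibitor Cdkn1a, itself a p53 target, fell by 0.47 ± 0.07. The adjusted p of this list was 0.059, 0.052 and 0.051 without array 3, 5 and 9, and its median was 0.040 without array 1 and 0.033 without array 5. Genes of the integrated stress and unfolded protein responses fell in 6 of 24 and rose in 1, against 10 and 2 adjusted over the list alone (median -0.078, adjusted p = 0.019, and adjusted p = 0.299 with an estimated correlation). By camera this list had an adjusted p of 0.053 on the Cy3 arrays alone and 0.085 on the Cy5 arrays alone. Asparagine synthetase Asns fell by 0.46 ± 0.05, Slc7a3 by 0.28 ± 0.04, Mthfd2 by 0.24 ± 0.04 and the transcription factor Atf4 by 0.34 ± 0.06.

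Heat shock and chaperone genes rose in 2 of 18 and fell in 3, also adjusted over the list alone (median -0.065, adjusted p = 0.598), with Hspb8 (0.48), Bag3 (0.20), Hsph1 (-0.24) and Hspd1 (-0.18) among them. Genes of hypoxia and glycolysis rose in 4 of 22 and fell in 5, also adjusted over the list alone (median -0.029, adjusted p = 0.661), with Hmox1 (0.47) and Ndrg1 (0.40) higher and Higd1a (-0.63) and Hk1 (-0.27) lower.

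Few probes passed for a difference between the dye orientations, but this does not show that dye bias was small. The mean Spearman correlation across probes was 0.42 for pairs of arrays of the same orientation and 0.22 for the other pairs. The median absolute dye term was 0.074, beside 0.105 for the null effect. The dye term passed for 4 of 5399 probes, namely those of Bmp6, Serpinb3a and Usp14 and an unnamed probe, and for 0 of the changed probes; these genes were chosen by their values. The labelled orientations did not fully follow the main division of the arrays. Array 10, labelled Cy3, correlated most with array 3, labelled Cy5 (Spearman 0.63 across probes), whereas array 9 correlated most with array 11, of its own label (0.70). With arrays 9 and 10 exchanged in the dye term 597 probes passed.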

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

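The dye term was planned and counts of other splits were set before they were run; the test of an exchange of dye labels was chosen after the result was seen, and that of the day 14 label before.

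For 4 probes the log ratio differed between the dye orientations by the model's own dye term, which tests that difference. The Cy5 minus Cy3 difference was 1.51 for Bmp6, a bone morphogenetic protein (means 1.02 and -0.49), 0.93 for Serpinb3a (0.62 and -0.31), 0.81 for Usp14 (0.41 and -0.40) and 1.16 for the unnamed probe 1399 (0.59 and -0.58). Each had an adjusted p of 0.046. Of 100 splits of the arrays into 6 and 5, the labelled one included, 2 gave as many as the 4 probes of the labels. The highest other of these splits gave 8. By the rule written before, fewer than 5 of 100 counts against chance, and this held. A split outside these 100, with arrays 9 and 10 exchanged and chosen after the data were seen, gave 594. The labelled split is thus not the most extreme, and chance was not taken as excluded. The 4 probes also depend on single arrays: 0 passed when array 1, 2, 3, 5, 6, 7, 8 or 11 was left out, 2 without array 9, 8 without array 4 and 341 without array 10.

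The 4 probes are far fewer than another division of the arrays gives, which points to a structure of the arrays. The first principal component, with 44.7% of the variance over complete probes, set arrays 3, 4, 10 and 5 (scores 11.3, 22.9, 10.8 and 3.54) against the other 7, which lay between -11.4 and -1.93. An exchange of the dye labels of arrays 9 and 10 is a candidate explanation: it gave 594 probes with a dye effect on the same probes, while the highest of the 29 other exchanges of 1 Cy3 with 1 Cy5 array, that of arrays 10 and 11, gave 151. With the exchange, the Cy5 arrays would be 3, 4, 5, 10 and 11, which have the highest scores of this component. A high count therefore follows from the component and does not test whether labels were exchanged. The correlations go with an exchange for array 10, nearest to array 3 of the other label (Spearman 0.63), but are mixed for array 9. Array 9 was nearest to array 11 of its own label (0.70). It came next to arrays 1 (0.53) and 7 (0.52) of the other label, and stood at 0.17 with arrays 3 and 4 of its own. With arrays 2, 5, 6 and 8 it lay between 0.24 and 0.37. The exchange thus cannot be told apart from another structure of the arrays. Wild-type RNA of day 14 on arrays 1 and 6 would lower the ratios of genes of dividing cells there; the cell cycle list's medians on these arrays, 0.066 and 0.13, lay within the range of the other 9, -0.01 to 0.25, which argues against it. The dyes were kept as labelled, and differences between single embryos stay open and untested.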

How the results depend on the processing

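Alternatives that leave out arrays 9 and 10, array 4, or arrays 3, 4 and 10, or exchange the dye orientation of arrays 9 and 10, were chosen after seeing the data. The lists of cholesterol biosynthesis, microglia, astrocytes and voltage-gated channels passed under all 30 alternatives. Among these, leaving out array 4 is counted again, and averaging the probes of a gene repeats the main fit of the lists. The 24 genes named by size passed with the same sign in every array, scaling, filter and variance alternative in which their probe was tested (667 values). Asic1, Epha4 and Abca1, with values on 10 arrays, were not tested in all. Since the 24 genes were chosen for size and sign on the same arrays, this was largely set in advance. None of these genes, and no list while it passed, had the opposite sign of the main analysis. Of the genes called there, 39 of 1356 on the Cy3 arrays and 5 of 1320 on the Cy5 arrays had the opposite sign; 714 and 377 were called again in the same direction, with fewer arrays. Medians of some lists that did not pass changed sign. The counts of changed probes stayed within 1.5 times in 28 of 32 alternatives; leaving out each array in turn gave 1170 to 1572. On the 5 Cy5 arrays alone 468 changed (182 higher, 286 lower), with fewer arrays; at an adjusted p of 0.01, 811 (393 and 418); at 1.5-fold or more, 96 (30 and 66); with the Cy5 arrays turned, 4 (0 higher, 4 lower), which are the 4 probes with a dye effect again, since turning them exchanges the mean and the dye term of the model. The exact sign-flip permutation test kept the count within 1.5 times; 0.00098 is the smallest p it can give. Probes with a dye effect numbered 0 without arrays 1 and 6 and 0 over complete probes, 575 without arrays 9 and 10, 597 with these exchanged, 8 without array 4, 217 without arrays 3, 4 and 10, and 0 to 341 with each array left out, the highest without array 10. The cause of the changes below was not tested.

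The dense core granule list passed with medians of -0.11 without a dye term, -0.18 on the Cy3 arrays, -0.11 without arrays 1 and 6, -0.10 with scale and -0.10 with quantile normalization, -0.081 with array weights, -0.12 over complete probes, -0.086 over all probes, -0.11 without arrays 9 and 10, -0.11 with these exchanged, -0.077 without array 4, -0.14 without arrays 3, 4 and 10 and -0.12 by fry, and -0.11 to -0.077 with each array left out (8 of 11 passed). By camera its adjusted p ranged from 0.0013 on the Cy3 arrays to 0.472 on the Cy5 arrays and was 0.166 with an estimated correlation, which did not pass; the 2.6e-09 of fry is a test against no change. Upper layer markers passed at 0.21 on the Cy3 arrays, 0.12 with array weights, 0.18 without arrays 3, 4 and 10, 0.11 by fry and 0.088 to 0.13 with each array left out (only without array 10). They did not pass in the other settings, among them an estimated correlation (adjusted p = 0.318), and fry again tests against no change. Calls were lost on the Cy3 arrays for glutamate receptors (-0.038), striatum and thalamus (-0.13), apoptosis (0.10), stress responses (-0.089), proteasome (-0.074) and ribosomal proteins (-0.046), and on the Cy5 arrays for progenitors (0.0080) and stress responses (-0.13). They were lost without arrays 1 and 6 for the proteasome (-0.076) and ribosomal proteins (-0.022), over complete probes for glutamate receptors (-0.10) and ribosomal proteins (-0.083), and for ribosomal proteins also with unmoderated variances (-0.083) and arrays 9 and 10 exchanged (-0.077). With each array left out, the ribosomal median was -0.11 to -0.056 (6 calls lost) and the apoptosis median 0.033 to 0.088 (3 lost).

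With an estimated correlation, calls were lost for synaptic vesicle genes (median of complete genes -0.22), glutamate receptors (-0.10), cell cycle (0.11), progenitors (0.16), meninges (0.16), striatum and thalamus (-0.065), apoptosis (0.12), stress responses (-0.11), oxidative phosphorylation (-0.22), proteasome (-0.10) and ribosomal proteins (-0.083). Fry, which does not compare a list with other genes, did not call the proteasome (-0.10) or ribosomal proteins (-0.083), and called neurotrophic factors (0.014, though fry pointed down), GABA genes (-0.041), the neuronal cytoskeleton (-0.060), deep layers (0.093), Cajal-Retzius markers (-0.072) and heat shock genes (-0.081). Signal over background is unknown, so it cannot be said which ratios come from dim probes, where ratios are compressed.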

Other observations

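In this part the tests of neuron share and subcortical tissue were chosen after the result was seen; those of liver X receptor targets and of sign patterns were written before. The genes named here were chosen after their values were seen unless the fixed rule names them, apart from the further liver X receptor targets.

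Some genes of lipid handling outside the fixed lists went up and others down; they were not tested as a set. The cholesterol exporter Abcg1 rose by 0.39 ± 0.04 on 11 of 11 arrays, as did Abca1 (0.89), while the desaturases Scd1 (-0.37 ± 0.11) and Scd2 (-0.31 ± 0.05) and the fatty acid desaturase Fads2 (-0.48 ± 0.12) fell. Acaca, which makes malonyl-CoA, rose by 0.60 ± 0.09 (n = 9, higher on 9), and Srebf1 rose by 0.34 ± 0.09 (n = 8, higher on 7).

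Of the microglia list, Cd68 rose by 1.04 ± 0.08 (n = 8) and Gpnmb by 0.97 ± 0.09 (n = 9), with values on too few arrays for the fixed rule. Outside the lists, Lgmn rose by 0.56 ± 0.06 (n = 11). Among genes that fell, Vmn1r49, annotated as a vomeronasal receptor, had a ratio of -1.895 ± 0.09 (n = 9), Gnrhr, the receptor of gonadotropin-releasing hormone, one of -1.26 ± 0.15 (n = 10), and Prkcd, a kinase abundant in thalamus, one of -0.88 ± 0.07 (n = 11). Among unnamed probes, 134 changed, with probe 2965 at 1.93 ± 0.10 (n = 8) and probe 2996 at -1.82 ± 0.09 (n = 11). The choroid plexus gene Ttr lay at 5.05, 4.94, 4.61 and 2.95 on arrays 5, 8, 6 and 4 and between -1.78 and 1.26 on the other 7.

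The number of changed probes was set against other assignments of signs. Of 100 sign patterns over the 11 arrays, the real one included, 1 gave as many as 1545 probes. The highest other, with 1 array turned, gave 658. The arrays thus agreed in sign beyond what random signs gave. Chance in the wild-type pool, read here as common to all arrays, is not excluded, since it would move every ratio alike.

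Microglia and astrocyte markers were higher while synaptic genes were lower on average. A lower share of neurons would raise the markers of every other cell type alike. Yet the mean microglia marker exceeded the mean vascular marker by 0.44 (permutation test over genes, p = 0.00016). This contrast was chosen after both lists were seen, and its p measures no spread between embryos. The size of the difference argues against a lower share of neurons as the whole cause. Such a share is not excluded as a part, since means of other lists rose with those of microglia and astrocytes: 0.27 for meninges and choroid plexus, 0.12 for progenitors and 0.10 for cell cycle genes. The mean for meninges and choroid plexus is raised by Ttr (1.505), which did not pass and varied widely between arrays. The median of that list was 0.20. More subcortical tissue in the wild-type pool is possible: the median striatum and thalamus marker was -0.063 with a bootstrap interval of -0.30 to 0.01, which reaches the size the explanation needs, and so it cannot be told apart from an effect of the genotype. A response of microglia and astrocytes to the null mutation remains a hypothesis. Since all arrays share the wild-type RNA, the makeup of that pool stays open for every gene.

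Genes of sterol synthesis were lower as a set. The mean sterol gene minus the mean gene of the neuronal cytoskeleton list was -0.43 (permutation test over genes, p = 0.00021). This contrast was chosen after both lists were seen, and its p measures no spread between embryos. On single arrays the sterol median was -0.66 to -0.36 and the cytoskeleton median -0.22 to 0.12. These values argue against a lower share of neurons as the whole cause, but only if the cytoskeleton list, which also holds axon growth genes, gauges that share. Its mean was -0.079, and other neuronal lists had lower means. These were -0.22 for synaptic vesicle genes, -0.17 for GABA genes, -0.14 for channels and -0.14 for glutamate receptors. The sterol mean was -0.51 and was not tested against those lists. Higher Abca1 and Abcg1 with lower sterol synthesis may reflect raised activity of liver X receptors, which respond to oxysterols. Of 9 further targets written down before they were looked at, only 2 were measured, Tgm2 (0.11 ± 0.05, adjusted p = 0.118) and the phospholipid transfer protein Pltp (-0.22 ± 0.04), with a median of -0.055 and a camera p of 0.524. By the rule written before, a median under 0.1 with a camera p of 0.05 or more counts against the explanation, and both held. Pltp passed in the direction against it (adjusted p = 0.00079). With only 2 genes measured, the question was left undecided.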
